A study of Mus musculus with 6 samples.

How the data were processed

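RNA from 6 samples of the mouse Leydig cell line TM3 was sequenced after 48 h with either vehicle or pyrotinib. Per the labels' protocols, 3 libraries came from cells given 0.1‰ dimethyl sulfoxide (DMSO) and 3 from cells given 100 nM pyrotinib. Messenger RNA was captured on oligo-dT beads, fragments of 370 to 420 bp were selected and both ends were read for 150 bp on a NovaSeq instrument. The protocol describes no step that marks the strand, and whether the counts separate a gene from an antisense partner is not given in the sources used here.

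The deposited table of counts gives whole-number reads per gene for each library. Per the submitters' processing notes, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used with genome build mm10. The notes as used here give no roles, order or settings. The annotation release, strand setting and treatment of reads that map to several places are not given in the sources used here. A second deposited table gives FPKM per gene. In it, 1 library size per column accounts for all genes, and that size was between 93.9% and 99.9% of the column's total in the count table. How the authors set it is not given in the sources used here. Of the 54532 gene identifiers, 54495 were found in GENCODE release M21, and 98.3% of those had identical positions there. Coordinates are those of the deposited table.

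Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), libraries were scaled by TMM, and the groups were compared with the two-sided quasi-likelihood F-test without a replicate block. P-values were adjusted by Benjamini-Hochberg over the 14125 genes tested, with a threshold of 0.05. Expression is given as TMM-scaled CPM, mean ± SD of 3 libraries. Standard errors of log2 fold changes are approximate: the absolute log2 fold change divided by the square root of F. A gene with no reads in a library is compared with the level of 3 counts, 0.186 to 0.200 CPM; this limit covers counting error only.

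Before the data were examined, 35 gene lists were fixed from textbook pathways, markers of other testicular and stromal cell types and signs of RNA quality. The 32 lists with at least 5 tested members were compared with the remaining genes by camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, two-sided, and adjusted over the lists. The same test with an estimated correlation, and fry, were alternatives. Beside each list stand the members past the threshold over all genes and after adjustment over the list alone.

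Genes named in the text were chosen by a rule fixed at the same time. It takes, among protein-coding genes past the threshold with a mean of at least 5 CPM and no overlap between groups, the 10 with the largest rise and the 10 with the largest fall. Symbols made of Gm and a number, or ending in Rik, were left out. It also takes up to 4 members of each list with the smallest adjusted p, and always Star, Cyp11a1, Hsd3b1, Hsd3b6, Cyp17a1, Hsd17b3, Lhcgr, Nr5a1, Egfr, Erbb2, Erbb3 and Erbb4. A gene with fewer than 10 reads over all libraries is given as reads. Other list members are named only with their values, and genes from outside the rule are said to be so.

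The labels give both groups replicates 1 to 3. They describe the cells as seeded in 6-well plates but do not say whether replicates are separate cultures, so p-values measure only the spread between these libraries. No 2 libraries of a group were identical: chi-square per degree of freedom between them ran from 4.16 to 16.3.

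The alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, median-ratio and upper-quartile scaling, 2 other count filters, a replicate block, leaving out each library, thinning to the shallowest library, limma-trend on log2 of the FPKM table (pseudocount 1 or 0.1 with a mean FPKM of at least 0.5, and pseudocount 1 with no filter), stricter thresholds and protein-coding genes alone. Chosen after seeing the data were a correction for transcript GC content (a lowess curve of span 0.3 for each library, taken from GENCODE M21 transcripts), the same followed by one for transcript length, pyrotinib replicate 2 alone against DMSO, and the GC correction without DMSO replicate 2.

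The edgeR test was tested on simulated data with 14125 genes, 200 of them changed. It recovered 54.0% of 50 genes changed 1.5-fold, 82.0% of 50 changed 2-fold, 94.0% of 50 changed 3-fold and 98.0% of 50 changed 4-fold; 4.09% of its calls were unchanged genes. With a GC trend added to pyrotinib replicates 1 and 3, it called 35 of 13925 unchanged genes, and 14 after the GC correction. The simulated trend, 0.02 log2 units per percentage point, was weaker than the observed slopes of -0.25 and -0.29 per 10 points. The 200 changed genes were also far fewer than the 3667 called in the data. These counts therefore do not give the number of false calls from the GC trend in the data.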

Results

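TM3 is a line of immature mouse Leydig cells, the testicular cell type that makes testosterone. Pyrotinib is an irreversible inhibitor of the kinases of the ErbB receptor family (EGFR, HER2 and HER4) used against HER2-positive breast cancer. The series concerns its toxicity to the male reproductive system. Poly(A) RNA was profiled in 3 DMSO and 3 pyrotinib samples after 48 h, with the drug at 100 nM. Library totals were 15005737, 16171030 and 16113180 counts for DMSO replicates 1, 2 and 3 and 15488289, 16118922 and 15743446 for pyrotinib. The first principal component held 52.3% of the variance and separated the groups, with DMSO at -19.0, -39.1 and -22.6 and pyrotinib at 29.4, 15.8 and 35.5.

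With pyrotinib, 12 of 19 endoplasmic reticulum chaperone and unfolded protein response genes, 23 of 24 mitotic genes and the transferrin receptor were lower, and all 12 tested mitochondrially encoded mRNAs were higher. The shifts of these 3 lists by camera were lost with an estimated correlation (adjusted p = 0.417, 0.351 and 0.417 with an estimated correlation). In all, 3667 of 14125 genes changed (26.0%), with 1862 higher and 1805 lower. Most changes were small: the median was 1.41-fold, 1335 genes changed at least 1.5-fold and 436 at least 2-fold. Groups did not overlap for 40.9% of tested genes, where chance gives 10.0% for 3 against 3. The count was 1956 without DMSO replicate 2 and 2164 without pyrotinib replicate 3, and 1228 genes were higher without DMSO replicate 3. With no filter on FPKM, limma-trend called 561 genes, 224 higher and 337 lower (39.9% higher, against 50.8% in the edgeR test).

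Of the 32 tested lists, 15 were shifted by camera, 2 upward and 13 downward. None passed with an estimated correlation, where 4 had an unadjusted p under 0.05. For NF-kB and cytokines the estimated correlation was -0.027, below the preset 0.01, yet the unadjusted camera p rose from 0.00019 to 0.015. In camera, an estimated correlation limits the test to the residual degrees of freedom, which are few with 6 libraries in 2 groups. A preset correlation takes them from the number of genes instead. Estimates lay on both sides of the preset 0.01, up to 0.78 for mitochondrially encoded genes. A call lost with an estimated correlation, here and below, therefore cannot decide whether correlated genes account for the shift. By fry, which does not compare a list with other genes, 11 passed, 9 of them among the 15; the others were p53 targets and ribosome biogenesis and MYC targets. The plot of list members shows each tested gene of these 15 lists.

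**Figure D1:**
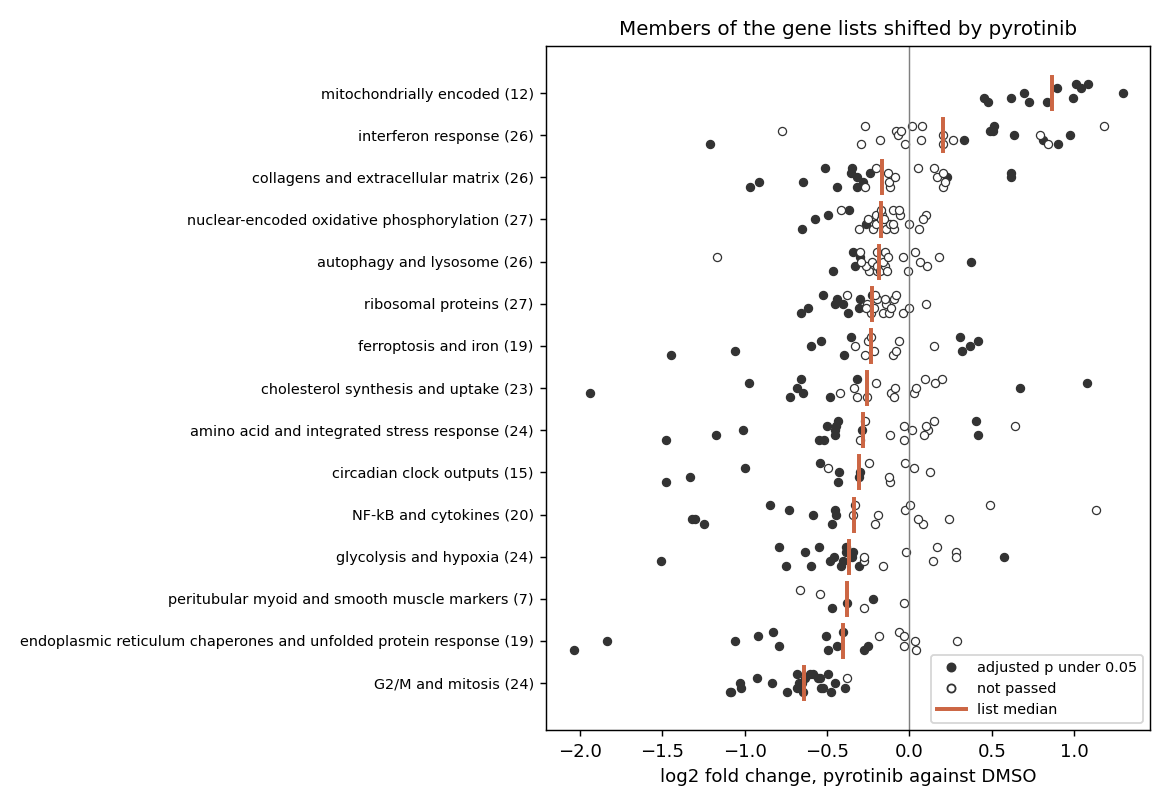
Log2 fold changes (x axis, pyrotinib against DMSO) of the tested members of the 15 shifted lists (y axis, number tested in parentheses). Filled points passed the edgeR threshold and lines are list medians, from -0.64 for G2/M and mitosis to 0.86 for mitochondrially encoded genes.

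Of the 4 ErbB receptors, Erbb3 passed the edgeR test and Egfr and Erbb2 did not. Egfr (ENSMUSG00000020122), at chromosome 11, 16752203 to 16918158 (mm10), was the most abundant at 669 ± 20.8 CPM with DMSO and 674 ± 26.9 with pyrotinib (log2 fold change 0.01 ± 0.08 SE, adjusted p = 0.923). After a GC and length correction its log2 fold change was -0.16 (adjusted p = 0.049). Erbb3 rose 1.52-fold, from 7.20 ± 0.262 to 10.9 ± 0.659 CPM (adjusted p = 0.0092). Erbb2 gave 70.2 ± 8.24 and 84.9 ± 8.86 CPM (1.21-fold, adjusted p = 0.055). Erbb2 passed after the GC correction (adjusted p = 0.0016) and with the replicate block (adjusted p = 0.035). Without DMSO replicate 2 its rise was 1.13-fold (adjusted p = 0.294). Erbb4 had 0 reads in every library. Of 14 tested ErbB receptors, ligands and regulators, 4 rose and 2 fell (5 and 3 adjusted over the list alone), and the list was not shifted (adjusted p = 0.451). Errfi1, a feedback inhibitor of EGFR, rose 1.56-fold (adjusted p = 9.5e-05). Lrig1, a negative regulator of ErbB receptors, fell 1.29-fold and its relative Lrig3 1.42-fold.

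Genes read as outputs of ERK signalling moved both ways. Among 24 in the list of ERK feedback and immediate early genes, 8 fell and 4 rose, the same numbers adjusted over the list alone. Egr1, an immediate early transcription factor, fell 2.23-fold from 334 ± 22.4 to 150 ± 13.5 CPM (log2 fold change -1.16 ± 0.09 SE, adjusted p = 2.7e-07). Fos fell 2.31-fold (adjusted p = 0.00022), and Ier3 1.93-fold. Spry1, a feedback inhibitor of the pathway, fell, with a log2 fold change of -0.68. The 4 that rose, named after their values were seen, were Fosl1 (1.86-fold), Spred2 (log2 fold change 0.53), Ccnd1 (1.39-fold) and Spred1 (0.38). The list was not shifted (adjusted p = 0.139 by camera, adjusted p = 0.682 with an estimated correlation). It passed camera without DMSO replicate 2 (adjusted p = 0.047). Junb, another immediate early gene, fell 2.95-fold, from 195 ± 37.9 to 66.2 ± 15.5 CPM.

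Mitotic genes fell together. Of 24 G2/M and mitosis genes, 23 fell and none rose (24 adjusted over the list alone), with a median log2 fold change of -0.64 (adjusted p = 7.5e-17 by camera, adjusted p = 0.351 with an estimated correlation). Bub1b, a spindle checkpoint kinase, fell 2.12-fold (52.9 ± 6.15 to 24.9 ± 0.543 CPM, adjusted p = 3.3e-06). Kif23, needed for cytokinesis, fell 2.03-fold, Ube2c 2.04-fold and the proliferation marker Mki67 1.56-fold. In pyrotinib replicate 2 alone, 22 of the 24 passed. Of DNA replication and G1/S genes, 4 of 25 fell, with 2 adjusted over the list alone, and the list was not shifted (adjusted p = 0.129). Ccne1 fell 1.69-fold and Cdt1 1.30-fold, and the falls of Mcm3 and Chaf1a lost their calls after the GC correction (adjusted p = 0.054 and 0.067) and in most fits without 1 library (adjusted p up to 0.126 without DMSO replicate 2 and 0.21 without pyrotinib replicate 3).

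The p53 target list had 4 rises and 3 falls among 18 (5 and 3 adjusted over the list alone, adjusted p = 0.624 by camera). It passed fry upward (adjusted p = 0.011), with a median log2 fold change of -0.0011 and a mean of 0.04. Trp53inp1 rose 1.78-fold and Ccng1 1.47-fold, and Cdkn1a gave a log2 fold change of 0.06 (adjusted p = 0.672). In the BCL2 family and caspases, 2 of 21 rose and 3 fell, also adjusted over the list alone, with no shift (adjusted p = 0.871). The proapoptotic genes Bbc3 and Bax fell 1.61-fold and 1.56-fold, while Xiap, a caspase inhibitor, rose 1.41-fold. Their transcripts held 65.2%, 63.5% and 36.8% GC, and their log2 fold changes were -0.69, -0.65 and 0.49. After the GC correction these were -0.51, -0.49 and 0.21, and in pyrotinib replicate 2 alone -0.44, -0.29 and 0.24. Bax lost its call without DMSO replicate 2 (adjusted p = 0.057). Of 6 tested replication-dependent histones, 2 rose, Hist2h2be by 2.12-fold and Hist1h2bc by 1.91-fold (also 2 adjusted over the list alone, adjusted p = 0.443 by camera).

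Several steroidogenic genes had few or no reads. Star, which carries cholesterol into mitochondria, gave 2.27 ± 0.317 CPM with DMSO and 3.34 ± 0.921 with pyrotinib (1.47-fold, adjusted p = 0.168). Cyp11a1 had 19 reads over the 6 libraries, Cyp17a1 17 and Nr5a1 10, too few to be tested. Hsd17b3 had 3 reads, Hsd3b1 2 and Hsd3b6 and Lhcgr 0, so changes in these genes were not detectable at this depth. Among 15 tested genes of steroidogenesis and Leydig identity, 1 rose and 4 fell (the same adjusted over the list alone). The list was not shifted: adjusted p = 0.848 by camera, direction down, against a median of 0.02 and a mean of 0.03. Akr1c14, a hydroxysteroid dehydrogenase, rose 2.00-fold (15.1 ± 1.06 to 30.2 ± 5.71 CPM, adjusted p = 8.5e-05). Scarb1, a lipoprotein receptor that supplies cholesterol, fell (log2 fold change -0.59, adjusted p = 0.00054). Nr4a1 fell 1.44-fold and Fdxr 1.25-fold, and both lost their calls without DMSO replicate 2 (adjusted p = 0.053 and 0.12) and without pyrotinib replicate 3 (adjusted p = 0.052 and 0.11); Fdxr also did without DMSO replicate 3 (0.065), without pyrotinib replicate 1 (0.057) and after the GC correction (0.13).

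Cholesterol synthesis and uptake fell, with 8 of 23 genes lower and 2 higher, also adjusted over the list alone (median -0.26, adjusted p = 0.013 by camera, adjusted p = 0.472 with an estimated correlation). Without DMSO replicate 2, 5 genes were lower. The sterol enzymes Msmo1, Lss and Fdft1 fell 1.96-fold, 1.65-fold and 1.56-fold, and Insig1, which restrains the pathway, had a log2 fold change of -0.68. The members that rose, named after their values were seen, were the sterol enzymes Tm7sf2 (log2 fold change 1.08) and Hsd17b7 (0.67). Fatty acid synthesis was not shifted (1 of 13 higher, 1 lower, also adjusted over the list alone, adjusted p = 0.919): Fads2 rose 1.53-fold, and Srebf1 fell 1.24-fold but lost its call after the GC correction (adjusted p = 0.053) and without DMSO replicate 1 (0.059) or 2 (0.071) or pyrotinib replicate 1 (0.071) or 3 (0.112).

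In the list of endoplasmic reticulum chaperones and unfolded protein response, 12 of 19 genes fell and none rose over all genes (12 and 1 adjusted over the list alone), with a median log2 fold change of -0.40 (adjusted p = 1.6e-05 by camera, adjusted p = 0.417 with an estimated correlation). Hspa5 (ENSMUSG00000026864), the main chaperone of the compartment, at chromosome 2, 34771970 to 34777547, fell 4.10-fold (log2 fold change -2.04 ± 0.17 SE, adjusted p = 5.1e-07). Its DMSO libraries held 944, 1966 and 1221 CPM and its pyrotinib libraries 343, 337 and 326. Manf fell 3.57-fold, from 37.8, 94.2 and 46.3 CPM to 15.1, 17.0 and 17.9. DMSO replicate 2 thus stood highest for both; without it, the log2 fold changes were -1.69 and -1.34 and the list median -0.33. Calr fell 1.89-fold and Hsp90b1 1.73-fold.

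Amino acid and integrated stress response genes fell as well: 11 of 24 were lower and 2 higher (12 and 3 adjusted over the list alone, median -0.28, adjusted p = 0.0022 by camera, adjusted p = 0.432 with an estimated correlation). Without DMSO replicate 1 the median was -0.16. Ddit3, a transcription factor of this response, fell 2.79-fold from 397 ± 59.9 to 142 ± 39.2 CPM (adjusted p = 2.9e-06). Ddit4 fell 2.26-fold, Nupr1 2.01-fold and Atf4 1.36-fold. Heat shock proteins were not shifted (adjusted p = 0.486 by camera): 4 of 13 rose and 2 fell, with 5 and 2 adjusted over the list alone. Dnaja1 rose 1.46-fold and Dnajb1 fell 1.44-fold. Chordc1 rose 1.34-fold but lost its call after the GC correction (adjusted p = 0.31) and without DMSO replicate 3 (0.051) or pyrotinib replicate 1 (0.058). NRF2 and antioxidant genes were not shifted (2 of 22 higher, 2 lower, also adjusted over the list alone, adjusted p = 0.871), with Gclm up 1.45-fold and Gstm1 down 1.37-fold.

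**Figure D2:**
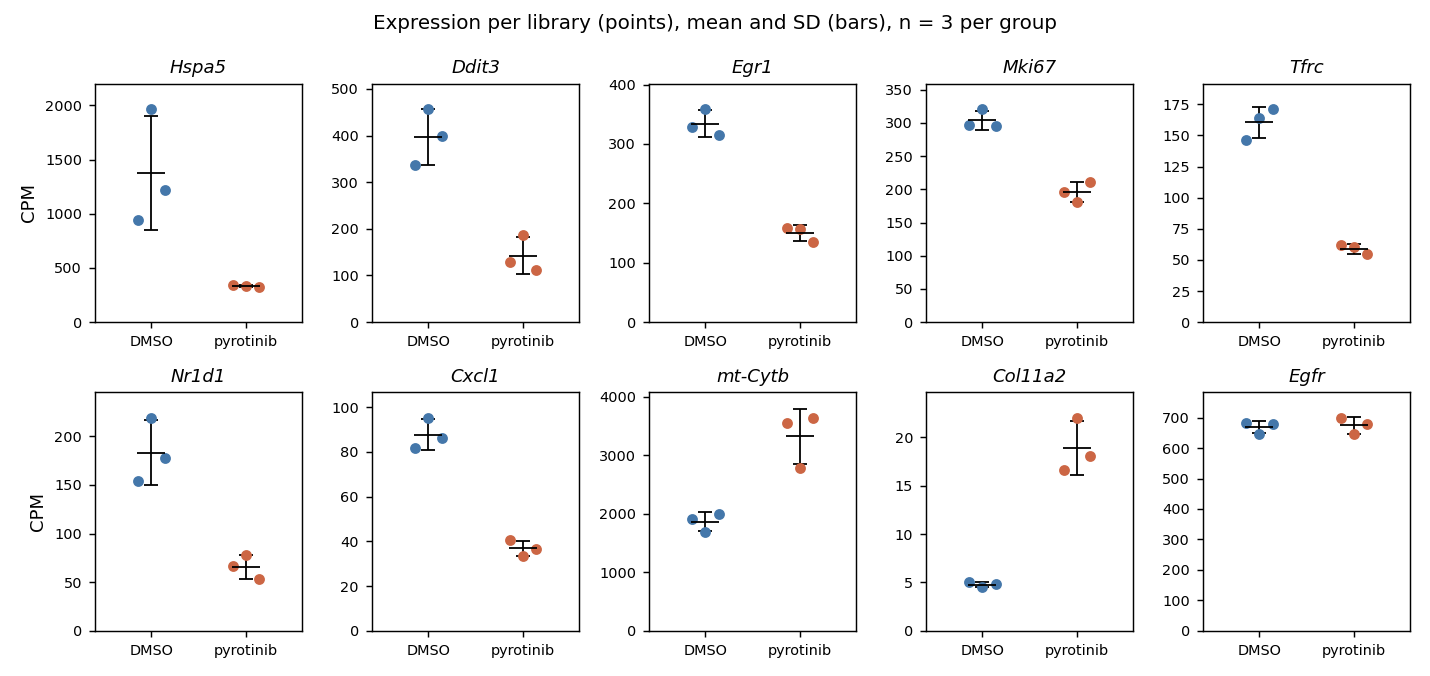
CPM (y axes, from 0) in each library by group (x axes) for 10 genes, with mean and SD of 3 libraries as bars. Hspa5 lay between 944 and 1966 CPM with DMSO and between 326 and 343 with pyrotinib, while Egfr gave means of 669 and 674.

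Mitochondrially encoded mRNAs rose in every tested case. All 12 were higher, also adjusted over the list alone, with a median log2 fold change of 0.86 (adjusted p = 4.0e-11 by camera, adjusted p = 0.417 with an estimated correlation). mt-Cytb rose 1.78-fold (1867 ± 161 to 3325 ± 476 CPM, adjusted p = 2.0e-05), mt-Nd5 1.99-fold, mt-Nd4 1.86-fold and mt-Nd6 2.46-fold. Mitochondrial genes took 2.16%, 2.03% and 2.14% of counts in the DMSO libraries and 3.49%, 2.70% and 3.60% in the pyrotinib libraries (two-sided exact permutation p = 0.1, the smallest this design can give). Pyrotinib replicates 1 and 3, with the higher shares, also carried a trend by GC content: per 10 percentage points of transcript GC, expression relative to DMSO changed by -0.25, -0.02 and -0.29 log2 units in pyrotinib replicates 1, 2 and 3, against -0.01, 0.02 and -0.01 in DMSO. In pyrotinib replicate 2 alone the list median was 0.54 with 6 of 12 genes past the threshold, and after the GC correction it was 0.59.

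**Figure D3:**
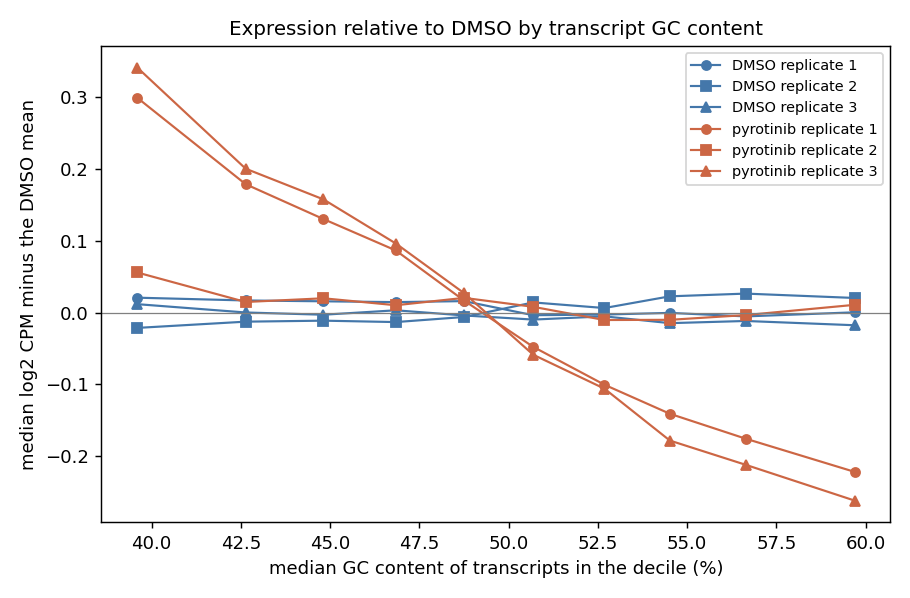
Median log2 CPM minus the DMSO mean (y axis) for protein-coding genes in 10 bins of transcript GC content (x axis, %), one line per library. In the bin lowest in GC, pyrotinib replicates 1 and 3 lay at 0.30 and 0.34 and pyrotinib replicate 2 at 0.06.

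Of 27 nuclear-encoded oxidative phosphorylation genes, 5 fell and none rose, also adjusted over the list alone (median -0.17, adjusted p = 0.0031 by camera, adjusted p = 0.472 with an estimated correlation). Cycs, cytochrome c, fell 1.57-fold, Cox5b 1.49-fold and Atp5o 1.41-fold, and Atp5b had a log2 fold change of -0.26. All 4 calls were lost without pyrotinib replicate 3 (adjusted p = 0.107, 0.086, 0.17 and 0.068). Other losses were without DMSO replicate 1 for Cycs and Atp5o (0.065 and 0.051), DMSO replicate 2 for Atp5o and Atp5b (0.15 and 0.094), DMSO replicate 3 for Cycs, Cox5b and Atp5b (0.058, 0.081 and 0.070) and pyrotinib replicate 1 for Cox5b, Atp5o and Atp5b (0.106, 0.15 and 0.0998). Ribosomal proteins fell slightly, with 10 of 27 lower and none higher (12 lower adjusted over the list alone, median -0.23, adjusted p = 1.8e-05 by camera, adjusted p = 0.523 with an estimated correlation). Rpl8 fell 1.58-fold and Rpl11 1.53-fold; both have pseudogenes that can share reads. After the GC correction the medians of the oxidative phosphorylation and ribosomal protein lists were -0.21 and -0.19. In pyrotinib replicate 2 alone they were -0.16 and -0.13 with 0 of 27 members past the threshold in each list, and Atp5o, Cox5b and Rpl11 had log2 fold changes of -0.02, -0.16 and -0.24. With the GC correction and without DMSO replicate 2 the ribosomal protein median was -0.12. Oxidative phosphorylation had 2 lower genes without DMSO replicate 2, 1 without DMSO replicate 3, 2 without pyrotinib replicate 1, 0 without pyrotinib replicate 3 and 10 without pyrotinib replicate 2. Ribosomal proteins had 6 without DMSO replicate 2 or 3 and 17 without pyrotinib replicate 2. Ribosome biogenesis and MYC targets were not shifted by camera (1 of 24 higher, 4 lower, also adjusted over the list alone, adjusted p = 0.128) but passed fry downward (adjusted p = 0.025), with Gnl3 down 1.66-fold.

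Glycolysis and hypoxia genes fell: 15 of 24 were lower and 1 higher (17 and 1 adjusted over the list alone, median -0.37, adjusted p = 2.9e-05 by camera, adjusted p = 0.472 with an estimated correlation). Vegfa, the angiogenic factor, fell 1.68-fold from 355 ± 28.9 to 211 ± 17.0 CPM and Ndrg1 1.55-fold. Gapdh fell 2.84-fold, from 53.7 ± 25.5 to 18.9 ± 3.80 CPM; its many pseudogenes make this value uncertain, and DMSO replicate 2 was again highest at 82.1 CPM. Pdk1, which limits pyruvate oxidation, rose 1.49-fold. In pyrotinib replicate 2 alone the list median was -0.16, with 2 genes lower.

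Tfrc, the transferrin receptor, had the smallest p of all named genes. Tfrc (ENSMUSG00000022797), at chromosome 16, 32608920 to 32632794, fell 2.73-fold from 160 ± 12.7 to 58.8 ± 3.72 CPM (log2 fold change -1.45 ± 0.09 SE, adjusted p = 5.0e-08). Ftl1, a ferritin subunit with pseudogenes that can share reads, fell 2.08-fold. The iron importers Slc39a14 and Slc11a2 fell 1.51-fold and 1.45-fold. Of 19 ferroptosis and iron genes, 6 fell and 4 rose (7 and 4 adjusted over the list alone, median -0.23, adjusted p = 0.018 by camera, adjusted p = 0.351 with an estimated correlation). Autophagy and lysosome genes fell slightly (4 of 26 lower, 1 higher, also adjusted over the list alone, median -0.19, adjusted p = 0.011 by camera, adjusted p = 0.523 with an estimated correlation). There were 2 lower genes without DMSO replicate 2 or 3 or pyrotinib replicate 1, and 11 without pyrotinib replicate 2. The lysosomal enzymes Hexa and Ctsb fell 1.38-fold and 1.26-fold and Atg5 rose 1.30-fold, a call lost without DMSO replicate 2 (adjusted p = 0.055) or 3 (0.094) and without pyrotinib replicate 1 (0.107). Genes of FOXO and PI3K feedback were not shifted (2 of 19 higher, 5 lower, 4 and 5 adjusted over the list alone, adjusted p = 0.871). Txnip fell 1.62-fold and Gadd45a 2.04-fold, while the receptors Igf1r and Insr rose 1.35-fold and 1.30-fold.

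Cytokine and clock genes fell. NF-kB and cytokine genes had 9 of 20 lower and none higher (11 and 3 adjusted over the list alone, median -0.34, adjusted p = 0.00085 by camera, adjusted p = 0.325 with an estimated correlation). The chemokines Cxcl1 and Ccl2 fell 2.38-fold and 2.49-fold (adjusted p = 3.0e-07 and 1.3e-05), and Tnfaip3 1.66-fold, and Vcam1 had a log2 fold change of -0.58. Of 15 circadian clock outputs, 8 fell, also adjusted over the list alone (median -0.31, adjusted p = 0.00013 by camera, adjusted p = 0.325 with an estimated correlation). Nr1d1, a clock repressor, fell 2.78-fold from 183 ± 32.9 to 65.9 ± 12.4 CPM, Per1 2.52-fold, Ciart 2.00-fold and Per3 1.34-fold.

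Interferon response genes rose: 8 of 26 were higher and 1 lower (9 and 1 adjusted over the list alone, median 0.20, adjusted p = 0.034 by camera, adjusted p = 0.472 with an estimated correlation). Oasl2 rose 1.86-fold, Trim30a 1.76-fold, Xaf1 1.55-fold and Ifit2 1.40-fold; the fall, named after its value was seen, was in the chemokine Cxcl10 (log2 fold change -1.21). The call was lost without DMSO replicate 1 (adjusted p = 0.094) and without pyrotinib replicate 1 (adjusted p = 0.061, median 0.12, 5 genes higher). The median was 0.35 without DMSO replicate 3 and 0.32 without pyrotinib replicate 2, and 4 genes were higher without DMSO replicate 2.

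Matrix genes changed in both directions. Among 26 collagens and extracellular matrix genes, 11 fell and 3 rose (12 and 5 adjusted over the list alone, median -0.17, adjusted p = 0.015 by camera, adjusted p = 0.417 with an estimated correlation). Fbln1 fell 1.95-fold (346 ± 0.785 to 177 ± 8.42 CPM) and Col6a3 1.56-fold, while the collagen cross-linking enzymes Lox and Loxl2 each rose 1.53-fold. The list's call was lost after the GC correction (adjusted p = 0.17). Matrix metalloproteinases and the plasminogen system were not shifted (2 of 17 higher, 3 lower, 3 and 3 adjusted over the list alone, adjusted p = 0.595). Mmp9, a gelatinase, fell 2.65-fold from 80.1 ± 4.40 to 30.3 ± 3.82 CPM, and Mmp2 1.51-fold; the inhibitor Timp3 rose 1.53-fold. TGF-beta and BMP response genes were not shifted (4 of 18 higher, 6 lower, 5 and 6 adjusted over the list alone, adjusted p = 0.848): Tgfb2 rose 1.59-fold and Ltbp2 fell 1.45-fold. For YAP and SRF targets, with 3 of 17 higher and 4 lower (4 and 6 adjusted over the list alone), the adjusted p was 0.919; Crim1 rose 1.83-fold and Cyr61 fell 1.42-fold.

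Several large rises lay outside these lists. Col11a2 (ENSMUSG00000024330), a fibrillar collagen chain at chromosome 17, 34039437 to 34066685, rose 3.97-fold from 4.76 ± 0.261 to 18.9 ± 2.77 CPM (log2 fold change 1.99 ± 0.16 SE, adjusted p = 3.9e-07). Angptl7 rose 3.12-fold, Ikzf2, an Ikaros family zinc finger factor, 2.98-fold, the potassium channel gene Kcnk2 2.70-fold and Wisp2 2.55-fold. Thbd, thrombomodulin, rose 2.61-fold from 28.3 ± 2.64 to 74.0 ± 3.65 CPM (adjusted p = 2.4e-07). Lrif1, Zfp595 and Zfp994, with transcripts of 33.4%, 37.8% and 37.9% GC, rose 2.54-fold, 2.44-fold and 2.44-fold. Their rises were 1.98-fold, 2.03-fold and 2.04-fold after the GC correction. In pyrotinib replicate 2 alone they were 1.83-fold, 1.85-fold and 2.08-fold. Among the falls, the exchange factor gene Arhgef39 fell 2.92-fold, the ion channel gene Asic3 2.75-fold and Disp2 2.74-fold.

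Among markers of other cell types, 7 of 11 peritubular myoid, 6 of 15 Sertoli and 5 of 12 endothelial genes could be tested. For steroidogenesis and Leydig identity it was 15 of 24. Peritubular myoid and smooth muscle markers fell (3 of 7 lower, 4 adjusted over the list alone, median -0.38, adjusted p = 0.019 by camera, adjusted p = 0.432 with an estimated correlation). Mylk fell 1.39-fold and Smtn 1.30-fold, and Tpm1 fell 1.16-fold but lost its call in every fit without 1 library except that without pyrotinib replicate 2 (adjusted p from 0.100 to 0.16). The list shares 5 genes with YAP and SRF targets, and its call was lost without DMSO replicate 1 (adjusted p = 0.050). Of 6 tested Sertoli cell markers, Wt1 and Inhbb rose 1.35-fold and 1.66-fold and Clu fell 1.44-fold (2 and 1 also adjusted over the list alone, adjusted p = 0.897). None of 5 endothelial markers passed, also adjusted over the list alone (adjusted p = 0.871 by camera). Too few macrophage (4), germ cell (2) and adipocyte (2) markers were tested for a list test; no macrophage or germ cell marker passed over all genes, and 1 germ cell marker did adjusted over the list alone. Lpl, lipoprotein lipase, rose 1.36-fold.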

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

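The GC correction, the GC and length correction, pyrotinib replicate 2 alone and the GC correction without DMSO replicate 2 were chosen after seeing the data. Of 131 named genes past the threshold, 110 kept their call and direction in all 6 fits that left out 1 library, 125 after the GC correction and 130 with DESeq2; of the 15 shifted lists, 13 and 14 did in the first 2 of these. The 21 genes that lost it leaving out 1 library were Atg5, Sqstm1, Bax, Mcm3, Chaf1a, Srebf1, Chordc1, Hspa8, Srxn1, Txn1, Cycs, Atp5b, Cox5b, Atp5o, Tpm1, Nolc1, Odc1, Utp20, Nr4a1, Fdxr and Lats2. No called list or named gene changed direction under any alternative. Lists also lost their call with FPKM filtered on its mean (interferon response, ferroptosis and iron), with no count filter (myoid markers), with no FPKM filter (myoid markers again), in pyrotinib replicate 2 alone (interferon response, autophagy), with the GC correction (collagens), with it and without DMSO replicate 2 (those 3 and myoid markers) and with fry (cholesterol, autophagy, glycolysis, oxidative phosphorylation, ribosomal proteins, interferon response). Depth limits Cyp11a1, Cyp17a1, Nr5a1, Hsd17b3, Hsd3b1, Hsd3b6 and Lhcgr, which had too few reads to test. The count of changed genes was 3371 with DESeq2, 3651 with limma-voom, 3661 and 3668 with the other scalings, 3773 and 3679 with the other count filters, 3663 after thinning, 3356 for protein-coding genes alone and 3962 after the GC correction, which called 2962 of the 3667 genes in the same direction. Leaving out 1 library gave 1956 (968 higher, 988 lower, without DMSO replicate 2) to 5226 (2615 and 2611, without pyrotinib replicate 2); fewer samples enter these fits, but the cause of the rise was not tested. FPKM gave 2179 changed genes (916 higher) with a pseudocount of 1, 2185 (927) with 0.1 and 561 (224 higher, 337 lower) with no filter; the cause was not tested. Pyrotinib replicate 2 alone, assumed to vary like DMSO, gave 968 (468 and 500), and 99.8% of the genes called with all libraries had the same sign. Those genes were called in a fit that held pyrotinib replicate 2 and the same DMSO libraries. Of the 3667, 3462 did not overlap between groups. The shared sign was therefore largely fixed in advance and is not a separate check. The medians of pyrotinib replicate 2 alone were over 1.5 times nearer 0 than with all libraries for glycolysis (-0.16), cholesterol (-0.14), autophagy (-0.08), ribosomal proteins (-0.13), myoid markers (-0.22) and, upward, mitochondrially encoded genes (0.54). The GC correction without DMSO replicate 2 gave 1235 higher genes. An adjusted p under 0.01 left 1877 (954 and 923), a fold of at least 1.5 left 1335 (708 and 627) and of at least 2 left 436 (213 and 223). With an estimated inter-gene correlation 0 lists passed, at unadjusted p under 0.05 for G2/M and mitosis (0.041), ferroptosis and iron (0.044), NF-kB and cytokines (0.015) and circadian clock outputs (0.020). Same-numbered libraries of the 2 groups deviated together weakly at most (correlations of 0.005, 0.076 and 0.023, against -0.072 to 0.056 for different numbers). With the replicate block 4265 genes (2124 and 2141) and 15 lists passed. The labels do not say whether equal numbers were handled together, so a shared replicate effect stays open.

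Results that had not passed turned direction as follows, by the list's test or the gene's log2 fold change; the cause was not tested. Values for lists are medians of log2 fold changes. Steroidogenesis and Leydig identity gave 0.027 (FPKM, no filter), 0.072 (GC correction), 0.11 (GC and length) and 0.047 (GC correction without DMSO replicate 2). Fatty acid synthesis gave -0.050 (no count filter), 0.017 (GC correction), 0.048 (pyrotinib replicate 2 alone), 0.0095 (GC correction without DMSO replicate 2), -0.045 (fry) and -0.13 to -0.0013 leaving out 1 library. BCL2 family and caspases gave 0.0038 (no count filter), 0.070 (pyrotinib replicate 2 alone) and -0.048 to 0.031 leaving out 1 library. YAP and SRF targets gave 0.015 and 0.020 (no count filter, CPM filter), 0.023 (thinned), -0.0032, -0.0031 and -0.0074 (FPKM with pseudocounts 1 and 0.1 and no filter), 0.024 (GC correction), 0.0021 (GC and length), -0.089 (pyrotinib replicate 2 alone), 0.0090 (GC correction without DMSO replicate 2), -0.035 (fry) and -0.069 to 0.014 leaving out 1 library. TGF-beta and BMP response gave 0.018 (GC correction), 0.017 (GC and length) and 0.0022 (pyrotinib replicate 2 alone). Endothelial markers gave 0.0068 (no count filter), -0.0027 (FPKM, no filter), 0.043 (GC correction without DMSO replicate 2) and -0.43 to 0.18 leaving out 1 library. Leaving out 1 library gave -0.013 to 0.047 for NRF2 and antioxidant, -0.038 to 0.018 for FOXO and PI3K feedback and -0.20 to 0.20 for Sertoli cell markers. Egfr gave -0.0067, -0.0068 and -0.0067 (FPKM), -0.090 (GC correction), -0.16 (GC and length), -0.050 (pyrotinib replicate 2 alone), -0.11 (GC correction without DMSO replicate 2) and -0.019 to 0.046 leaving out 1 library, with an adjusted p of 0.049 after GC and length correction as the only pass among these.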

Other observations

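The tests of transcription factor families, features within genes, mitochondrial RNA classes, GC slopes and chromosome bounds, the comparison with nuclear respiratory genes, and the fits with a GC correction or with pyrotinib replicate 2 alone, were chosen after the data were seen. Among 13 transcription factor families annotated in the deposited table with at least 10 tested members, the C2H2 zinc finger family rose: 171 of 428 genes were higher and 17 lower, with a median log2 fold change of 0.34 (adjusted p = 2.6e-11 by camera, adjusted p = 0.658 with an estimated correlation). Zfp65 rose 2.10-fold, Zfp763 1.88-fold and Klf2 2.01-fold. The family's transcripts had a median GC content of 43.8%. The ZBTB family rose (14 of 43 higher, 1 lower, adjusted p = 0.015 by camera, adjusted p = 0.658 with an estimated correlation), with Zbtb1 up 1.79-fold. The ZBTB median was 0.16, against 0.096 without DMSO replicate 2 and 0.096 in pyrotinib replicate 2 alone. The bHLH family fell (14 of 43 lower, 4 higher, adjusted p = 0.014 by camera, adjusted p = 0.658 with an estimated correlation). Mitf fell 1.67-fold and Srebf2, a regulator of sterol synthesis, 1.45-fold. The bHLH median was -0.21, against -0.19 without DMSO replicate 2 and -0.13 in pyrotinib replicate 2 alone. The members of these families were named after their values were seen.

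Non-coding features that overlap a protein-coding gene contributed many of the large falls. Of 1202 such features tested, 98 fell and 27 rose at least 2-fold, against 12 and 39 of 1155 features with no such overlap (two-sided Fisher's exact test across features, p = 2.0e-11, features are not independent replicates). Of the 98, 24 lay over a gene that itself fell, where 1582 of all 11755 tested protein-coding genes fell. Gm26762, at chromosome 7, 34224755 to 34230236, fell 8.03-fold from 31.3 ± 11.4 to 3.90 ± 1.59 CPM, while Gpi1, which it overlaps, had a log2 fold change of -0.38. Gm15344, on the same strand as Hsp90b1, which it overlaps, fell 10.5-fold against -0.79 for that gene. These features and Gpi1 were named after their values were seen, and how far the counts separate a feature's reads from those of the overlapping gene is not known. Without DMSO replicate 2, 53 fell and 10 rose at least 2-fold. Within the mitochondrial genome, 9 of 11 tested tRNA genes rose (median 1.18), while the 2 rRNA genes had a median log2 fold change of 0.02 and neither passed.

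The changes followed transcript GC content: in the fifth of protein-coding genes lowest in GC, 688 rose and 124 fell; in the fifth highest in GC, 133 rose and 540 fell. Pyrotinib replicates 1 and 3 carried this trend. Their slopes and that of pyrotinib replicate 2 spanned 0.27 log2 units per 10 points, against 0.038 among DMSO libraries, as a GC bias that differs between libraries would give. A treatment effect in all 3 pyrotinib libraries cannot be told apart from none: the criterion first stated for it, all 3 slopes below the lowest DMSO slope, was met, but pyrotinib replicate 2, at -0.020, met it by 0.0068, less than the DMSO SD of 0.021, and a margin of 1 SD was required only after the slopes were seen. As the whole cause of 3 shifts the trend is argued against: after the GC correction the ribosomal protein and nuclear oxidative phosphorylation medians were -0.19 and -0.21 (adjusted p = 0.00069 and 0.0072 by camera, whose calls without the correction were lost at adjusted p = 0.523 and 0.472 with an estimated correlation), and the C2H2 family median was 0.25 (adjusted p = 2.2e-08 by camera, the call without the correction being lost at adjusted p = 0.658 with an estimated correlation). The ribosomal protein median was nearer 0 when DMSO replicate 2 was also left out (-0.12, adjusted p = 0.026) and in pyrotinib replicate 2 alone (-0.13, 0 of 27 members past the threshold), so part of that shift may come from single libraries, and a response to the drug stays open.

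For the rise of mitochondrially encoded mRNAs, GC bias as the whole cause is argued against by the median of 0.59 after the correction, with 10 of 12 genes past the threshold and quartiles of 0.42 and 0.70. Pyrotinib replicate 2, whose GC slope was -0.020 against -0.25 and -0.29 in the other pyrotinib libraries, gave 0.54 on its own, with 6 of 12 genes past the threshold. A higher yield of all respiratory chain mRNAs is argued against by the nuclear-encoded members, at -0.21 after the correction. A response to pyrotinib, and a difference in how mitochondrial transcripts were captured or survived extraction, may both account for it and were not separated; the rRNA genes, at -0.29 after the correction, did not move with the mRNAs.

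The fall of endoplasmic reticulum chaperones does not rest on DMSO replicate 2 alone: without it the median was -0.33, and 9 of 19 genes passed. GC bias is argued against by a median of -0.37 after the correction. Pyrotinib replicate 2 alone gave -0.37, with 5 of 19 genes past the threshold. The level differed within the DMSO group, 944 to 1966 CPM for Hspa5, so a difference between the vehicle-treated samples may contribute to the size of the fall. A response to pyrotinib also stays open, and neither was tested further.

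The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 3667 changed genes (highest other 0), 1862 higher (highest other 0), 1805 lower (highest other 0) and 15 shifted lists (highest other 7), the real split being the 1 as large in each case. Chromosome medians of log2 fold change, against 10000 random sets of the same size, lay within 0.10 of 0 on all 20 chromosomes tested, the farthest being X at 0.10 (adjusted p = 0.0020). Chromosomes 7, 13, 17 and 18 also passed, at -0.07, 0.08, -0.04 and 0.08. This argues against a gain or loss of a whole chromosome in most cells.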
